A study of Drosophila melanogaster with 2 samples.

How the data were processed

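The data come from a chromatin immunoprecipitation sequencing (ChIP-seq) experiment on whole wandering third-instar larvae of Drosophila melanogaster, pooled males and females. The flies carry a transgene that makes the transcription factor Mio fused at its C-terminal end to green fluorescent protein (GFP), and the fusion protein was precipitated with an antibody against GFP, per the labels. Mio is an older name of Mondo, a basic helix-loop-helix leucine zipper protein that binds DNA with its partner Mlx, also called bigmax. Chromatin was sheared by sonication, per the labels. There was 1 group with 2 biological replicates, numbered 5 and 1 in the labels, and no treated or second group.

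Peak lists in the narrowPeak format were used. For each replicate, the deposited relaxed list (peaks together with background, made as input for the irreproducible discovery rate, IDR) was called on that replicate's alignments and a control alignment, per the text files deposited with the lists. A pooled relaxed list was called on the alignments of both replicates and the same control, and the optimal list was derived from both replicate lists and the pooled list. The control alignment itself was not analysed here. Since both replicates were called against the same control, errors of the control are shared by them. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. All lists were present in the dm6 and dm3 builds; dm6 was the main build, and coordinates were never converted between builds.

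The deposited signal value of each peak, whose scale is not given in the sources used here, is the authors' own measure and served only to rank peaks within a list or, at matched peaks, to compare the replicates. The deposited −log10 q-value was at its ceiling in all 1146 optimal peaks, so it did not rank them. Read depth per library is unknown, and intervals given here cover counting error over peaks or genes only.

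Positions were taken 1-based from the dm6 files and set against the Release 6 genome and the Ensembl release 115 annotation (BDGP 6.54). The largest peak end on the mitochondrial chromosome was 19524, which equals its reference length, and no peak end on another arm lay beyond that arm. A promoter was called bound when a transcription start site (TSS) of a protein-coding transcript lay within 500 bp of an optimal summit. For mitochondrial genes the annotated gene start stood in for the TSS. A peak near several genes counted for each of them. The annotation held 13981 protein-coding genes.

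Peaks were shared between replicates when their summits lay within 100 bp. The share among the strongest peaks of both lists was compared with 1000 random draws of as many peaks from each relaxed list (one-sided permutation test). Promoter position, chromosome share, sequence content and gene lists were compared by two-sided Fisher's exact tests, whose p-values are called exact p. Sequences were searched on both strands within 50 bp of a summit and in flanking windows of the same length centred 500 bp to either side. The 8 fixed sequences were CACGTG, the paired E-box (2 copies of CACGTG separated by 5 bp, with at most 2 mismatches in the 12 fixed bases), other CANNTG, GAGAG, TATCGATA, TGAGTCA or its reverse, CAGGTAG and CAGCTG. All 2080 strand-merged hexamers were searched too. P-values were adjusted by the Benjamini-Hochberg method within each family (8 sequences, 2080 hexamers, 23 gene lists). The signal of peaks with and without CACGTG was compared by a permutation test with 100000 resamples. Peaks and genes are not replicates, so these tests describe this peak list. Shares have 95% Wilson intervals.

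The groups, tests, gene lists, sequences and most alternatives were fixed before the data were examined. Named genes were those with a TSS within 500 bp of the summit of the 25 strongest optimal peaks, Mondo and its partner, and up to 4 members of each list with the strongest promoter peak. Because mitochondrial peaks held many of the first places, the 25 strongest nuclear peaks and a repeat of every result on nuclear peaks only were added after the mitochondrial peaks had been seen. Ranks quoted per replicate are those of a relaxed peak with its summit within 100 bp of the optimal summit; for the promoters of Mondo and bigmax they are those of the strongest relaxed peak within 500 bp of a TSS. Of the listed symbols, 3 (Phgdh, Psat and Tor) matched no single annotated gene and were left out.

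Alternatives were the dm3 lists, other overlap rules (1 bp, 50% of both peaks, summits within 50 or 250 bp), the strongest peaks of each replicate alone and of the pooled list, the 573 strongest optimal peaks, TSS distances of 200 and 1000 bp, the whole peak in place of the summit, and other backgrounds. For genes, a reach from 2000 bp before the gene to its end was tried, and for sequences windows of 25 and 100 bp. The pooled alternative is nearly the same set, since 1145 of the 1146 optimal peaks are among the 1146 strongest pooled peaks.

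The methods were tested on simulated data. CACGTG planted in 2% of windows came first among the 2080 hexamers. In that simulation both sets of windows came from random genome positions. They lacked the GC difference between real summits and flanks, so this place need not carry over to the real data. A simulated list of 85 genes with members 3 times as likely to be bound as other genes was recovered in 78% of runs, and with members 6 times as likely in 98%. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; plots used matplotlib 3.10.9.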

Results

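Binding of GFP-tagged Mio (Mondo), the fly relative of the vertebrate glucose-responsive factors MondoA and ChREBP, was profiled by ChIP-seq in whole wandering third-instar larvae in 2 biological replicates, numbered 5 and 1. The experiment maps where the tagged protein is found in the genome. It has no second condition, so the comparisons are between replicates, between bound and other positions, and between gene groups. The optimal list held 1146 peaks in dm6. Of these, 929 lay on the large autosomal arms, 187 on X, 1 on chromosome 4, 29 on the mitochondrial chromosome and 0 on Y. The relaxed lists held 29999 peaks in replicate 5, 30000 in replicate 1 and 28423 in the pooled data. The median width of an optimal peak was 360 bp. The number of reads per library is unknown, and signal values are the authors' own.

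The strongest optimal peaks were mitochondrial. They held 16 of the first 25 places and named 12 protein-coding mitochondrial genes, led by mt:CoI (rank 1, signal 3399, summit at position 1901 of chromosome M), mt:ND3 (rank 2, signal 3313, summit 5276) and mt:Cyt-b (rank 3, signal 2961, summit 10802). These 3 genes encode subunits of respiratory complexes, and all of these summits lay in coding exons. One dm6 interval from position 1 to 14170 carried these summits, and the 29 mitochondrial peaks formed 6 distinct intervals. The 29 mitochondrial peaks had a median signal of 690.2, against 97.5 for the nuclear peaks. The dm3 optimal list held 9 mitochondrial peaks, the best at rank 52. The best mitochondrial peak of replicate 1 was at rank 1 in dm6 and 28004 in dm3, and that of replicate 5 at rank 1 and 14. The order at the top thus differs between the deposited lists of the 2 builds; whether their pipelines treated the mitochondrial sequence alike is unknown, and so is what these ranks and signals measure. It also differed between replicates in dm6. Of the 29 mitochondrial peaks, 9 were matched in both, with a median signal of 1999 in replicate 5 and 222.5 in replicate 1, and 6 of the 12 genes had no matched peak in replicate 1.

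Among nuclear peaks, the strongest lay 34 bp upstream of Ugalt, a UDP-galactose transporter gene (X, 2703715 to 2704052, intergenic, signal 769.9, rank 21 in replicate 5 and 8 in replicate 1). The second (2L, 480929 to 481473, signal 722.8) lay in an intron of ush, and its nearest TSS, 1427 bp away, was that of cbt, a zinc finger gene known to be activated by Mondo and Mlx. It was followed by peaks at CG14100 (3L, 19590458 to 19590793, 107 bp upstream, signal 722.8), CG1888 (2R, 9547035 to 9547327, in the 5' UTR, signal 601.3) and PNPase, which encodes a mitochondrial RNA exonuclease (3R, 31404516 to 31404810, in an intron, signal 556). Other genes at the 25 strongest nuclear peaks included 3 mitochondrial ribosomal protein genes, mRpS23 (signal 516.2), mRpS10 (signal 419.8) and mRpL41 (signal 417.1). They also included eIF6, a ribosome assembly factor (signal 438.3), larp, an mRNA-binding protein (signal 524.3), Chro, a chromosomal protein that shares its peak with the TFIIH subunit gene Ssl1 (signal 447.7), and the Polycomb group gene ph-p (signal 420.8). Sox14, an ecdysone-responsive factor, had a signal of 399.1, and CHMP2B shared a peak with Tcs5 at a signal of 409.9. CenG1A shared the peak of mRpS23, Art3 that of mRpS10, and CG3437 shared a peak with CG3552 (signal 460.8). The peak at Drat (2R, 7530795 to 7531079, signal 462.8) was the one of these 25 with CACGTG within 50 bp of its summit.

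The tagged gene itself, Mondo, and its partner bigmax had no optimal peak at their promoters. The strongest relaxed peak at the Mondo promoter was at rank 1933 in replicate 5 and 3014 in replicate 1. The bigmax promoter was at rank 3354 in replicate 5 and at rank 540 in replicate 1, which is inside the 1146 strongest peaks of that replicate.

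The replicates shared 561 of their 1146 strongest peaks (49%, 95% interval 46.1 to 51.8%), against a median of 0.785% and a maximum of 2.01% in random draws of as many peaks from the relaxed lists (p = 0.000999, the smallest that 1000 draws can give, one-sided permutation test). Each draw takes a small part of a long list, so few shared peaks are expected in it even between lists that agree. The p-value shows only that strong peaks coincide more often than peaks drawn without regard to strength. Of the optimal peaks, 1034 were matched in both replicates. Across those peaks, which are not independent replicates, the signal of replicate 5 and of replicate 1 had a Spearman rho of 0.372 and a Pearson r of log10 values of 0.549. On nuclear peaks only, rho was 0.356 and r was 0.491 over 1025 peaks. Nearly all optimal peaks were among the 1146 strongest pooled peaks, and such a cut on joint signal can lower these correlations. Single genes could differ by far more than their place in the optimal list shows. The promoter peak of cbt ranked 141 in replicate 1 and 2132 in replicate 5, that of Idh3g, a TCA cycle enzyme subunit, ranked 566 in replicate 5 and 5507 in replicate 1, and that of vri, a clock gene, ranked 600 in replicate 5 and 12068 in replicate 1.

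**Figure D1:**
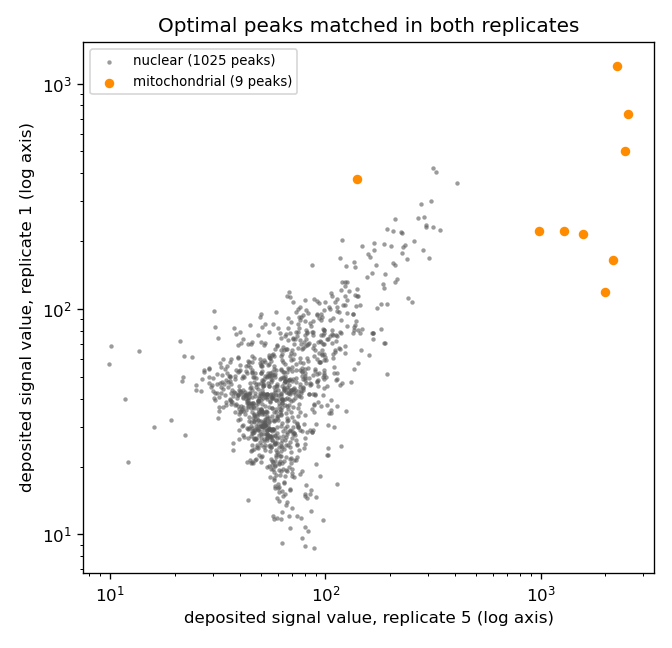
Deposited signal values of optimal peaks matched in both replicates, replicate 5 on the horizontal and replicate 1 on the vertical axis, both logarithmic and in the authors' signal units; each point is a peak. The 1025 nuclear peaks, from a list cut on signal, give a Spearman rho of 0.356. Most of the 9 matched mitochondrial peaks lie at the right, above the nuclear range of replicate 5.

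Optimal peaks lay close to gene starts. Of the 1146 summits, 651 (56.8%, 95% interval 53.9 to 59.6%) were within 500 bp of a protein-coding TSS, against 7091 of 27059 relaxed peaks outside the optimal list (26.2%). The odds ratio was 3.70 (p = 1.05e-100, Fisher's exact test), and 11.4% of random positions were as close. The median distance from a nuclear summit to a TSS was 275 bp. Of the 1117 nuclear summits, 11.5% fell in 5' UTRs, 46.6% in introns, 40.6% between genes, 0.985% in 3' UTRs and 0.358% in coding exons. A sample of 5000 relaxed summits had 6.48% in coding exons and 6.44% in 3' UTRs. In all, 863 of 13981 protein-coding genes (6.17%) had a bound promoter, 851 of them nuclear.

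The cytosolic ribosomal protein genes stood out among the fixed gene lists. Of 85 such genes, 34 had a bound promoter (40%, 95% interval 30.2 to 50.6%), against 5.97% of other genes (odds ratio 10.5, adjusted exact p = 2.76e-18). The leading members were RpS27 (3R, 25247415 to 25247621, signal 241.2), RpL7 (signal 222.8), RpL34b (signal 188.8) and RpL28 (signal 182.3). CACGTG lay within 50 bp of the summits at RpL7 and at RpL24, a further bound member. Among genes with any relaxed promoter peak, 44.2% of the ribosomal protein genes were bound, against 12.6% of other genes (adjusted exact p = 2.84e-10). With each replicate alone, 37.6% and 41.2% of the list were bound. None of 15 ribosome biogenesis genes, which include rRNA processing factors, was bound (95% interval up to 20.4%, adjusted exact p = 1).

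Glycolysis genes also carried more bound promoters than other genes, with 5 of 15 bound (33.3%, 95% interval 15.2 to 58.3%, odds ratio 7.64, adjusted exact p = 0.0121). Members with the strongest peaks were Gapdh2 (X, 15867861 to 15868132, signal 245.7), Eno (signal 128.4), Hex-A (signal 95.5) and Pgk (signal 90.4), with summits at −146, −222, −209 and −245 bp from a TSS (negative is upstream). The call held in 5 alternatives, among them the background of genes with any relaxed promoter peak. There, 55.6% of 9 glycolysis genes were bound, against 12.9% of other genes (adjusted exact p = 0.0337). Neither this background nor that of all genes was matched on gene expression, here or for the ribosomal protein genes. The glycolysis call rests on few genes. It was lost in replicate 5 alone (26.7%, adjusted exact p = 0.0911), in replicate 1 alone (20%, adjusted exact p = 0.187), among the 573 strongest optimal peaks (13.3%, adjusted exact p = 0.364) and with a TSS distance of 200 bp (13.3%, adjusted exact p = 0.398), and no promoter of the list was under a whole peak.

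The other lists of sugar and lipid metabolism did not pass the test. In the pentose phosphate pathway, 2 of 7 genes were bound, the transketolase gene CG8036 (signal 219.9) and Zw, which encodes glucose-6-phosphate dehydrogenase (signal 87.6, adjusted exact p = 0.249). Of 13 sugar-responsive genes tied to Mondo and Mlx, 2 were bound, cbt (signal 124) and Zw (adjusted exact p = 0.396). Stronger optimal peaks near cbt lay outside the 500 bp limit. Of 19 genes of fatty acid and triglyceride synthesis, 2 were bound, the phosphatidate phosphatase gene Lpin (signal 153.4) and AcCoAS (signal 81.2, adjusted exact p = 0.583). Sugar transport, trehalose and glycogen had 2 of 15, Pgm1 (signal 92.6) and Glyp (signal 90.2, adjusted exact p = 0.452), and gluconeogenesis and the polyol pathway had 1 of 11, Sodh2 (signal 75.8, adjusted exact p = 0.769). Among midgut digestive enzymes, 1 of 19 was bound, Mal-A5 (signal 146, adjusted exact p = 1).

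Mitochondrial and amino acid metabolism lists did not pass either. The TCA cycle had 3 of 18 bound, Fum1 (signal 120.1), mAcon1 (signal 78.7) and Idh3g (signal 77.8, adjusted exact p = 0.315), and oxidative phosphorylation 3 of 22, the ATP synthase gene blw (signal 116.2), ND-24 (signal 87.4) and COX6B (signal 74.3, adjusted exact p = 0.383). Amino acid and one-carbon metabolism had 3 of 14, aay (signal 140.5), Got2 (signal 111.7) and P5cr (signal 83.4, adjusted exact p = 0.235).

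Of the regulatory lists, the circadian clock had 3 of 10 bound, sgg (signal 178.5), Pdp1 (signal 130.9, with CACGTG at its summit) and vri (signal 75.1, adjusted exact p = 0.117). Insulin, TOR and AMPK signalling had 3 of 22, Sesn (signal 277), REPTOR (signal 192.3) and foxo (signal 82.3, adjusted exact p = 0.383). The lysosome, V-ATPase and autophagy list had 3 of 23, Vha44 (signal 127.3, with CACGTG at its summit), Vha36-1 (signal 91.7) and Atg18a (signal 88.1, adjusted exact p = 0.383), and the list of bHLH-zip and bHLH-PAS factors had 1 of 15, crp (signal 101.3, adjusted exact p = 0.833). In replicate 5 and replicate 1 alone, the clock share was 30% and 10%, the lysosome share 8.70% and 21.7%, the share of amino acid metabolism 7.14% and 21.4%, and that of the pentose phosphate pathway 28.6% and 14.3%, all without passing. With a reach from 2000 bp before a gene to its end, 4 lists that did not pass at promoters did so: the clock, amino acid metabolism and bHLH lists (adjusted exact p = 0.0417 for each) and insulin signalling (adjusted exact p = 0.0483). This reach covers more sequence in longer genes, and gene length was not adjusted for.

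No list of tissue markers passed the test for more bound promoters. The neuron list had 1 of 12, elav (signal 133.7, adjusted exact p = 0.769), and the salivary gland list 1 of 10, fkh (signal 189.5, adjusted exact p = 0.769). None of 10 fat body, 14 muscle, 12 haemocyte and 12 cuticle and epidermis markers was bound (adjusted exact p = 1 for each). None of 119 chemoreceptor genes was bound (95% interval up to 3.13%, against 6.23% of other genes, adjusted exact p = 0.00975). Only 7 chemoreceptor genes had any relaxed promoter peak, and against genes with such a peak the adjusted exact p was 1. The call was also lost among the 573 strongest optimal peaks (adjusted exact p = 0.364), with a TSS distance of 200 bp (adjusted exact p = 0.123) and with whole peaks (adjusted exact p = 0.183).

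**Figure D2:**
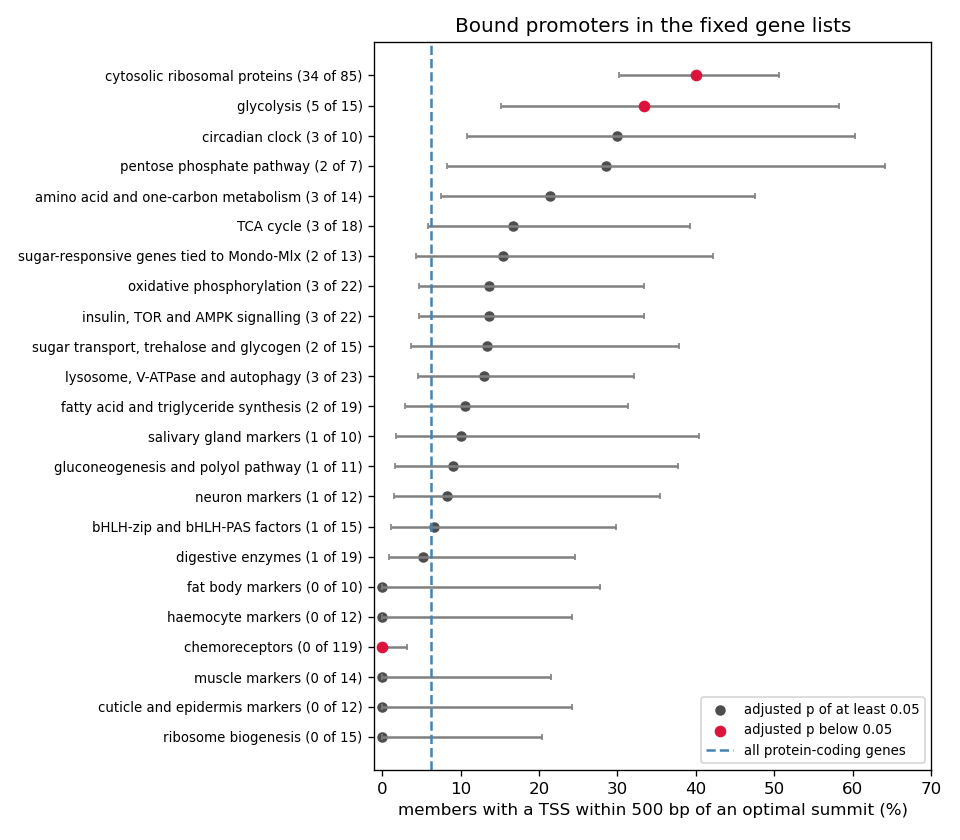
Share of each fixed gene list with a TSS within 500 bp of an optimal summit, in percent on the horizontal axis; points are shares, bars 95% Wilson intervals, and the dashed line marks the 6.17% of all protein-coding genes. Cytosolic ribosomal proteins (40%) and glycolysis (33.3%) lie above the line and chemoreceptors (0 of 119) below it with an adjusted p under 0.05, shown in red.

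The E-box CACGTG, the sequence that Mondo and Mlx are known to bind, was not enriched at the summits. It lay within 50 bp of 15 of 1146 summits (1.31%, 95% interval 0.795 to 2.15%) and in 36 of 2289 flanking windows (1.57%, odds ratio 0.83, adjusted exact p = 0.848). The paired E-box known as the carbohydrate response element was found at 3 summits and in 3 flanking windows (adjusted exact p = 0.652). Other CANNTG sequences were at 37% of summits and in 39.7% of flanks (adjusted exact p = 0.512). Of the remaining fixed sequences, GAGAG, the GAGA factor site, was at 14% and in 15.3% (adjusted exact p = 0.652), the AP-1 site TGAGTCA at 0.96% and in 1% (adjusted exact p = 1), the Zelda site CAGGTAG at 0.262% and in 0.568% (adjusted exact p = 0.652), and CAGCTG at 4.89% and in 5.2% (adjusted exact p = 0.848). One fixed sequence was enriched, TATCGATA, the DNA replication-related element of many housekeeping promoters, at 30 summits (2.62%) and in 7 flanking windows (0.306%, odds ratio 8.76, adjusted exact p = 2.21e-08).

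Among all hexamers, 211 were more frequent and 285 less frequent at summits than in the flanks, and CACGTG stood at place 1737 in the order of p-values. A/T-rich words led, with TTAAAA at 28% of summits and in 15.1% of flanks (odds ratio 2.18, adjusted exact p = 2.74e-15), followed by ATTTAA (25.7% against 14%) and AAATAT (27.8% against 15.8%). TTTAAA (18.1% against 8.61%), ATTTTA (25% against 14.6%) and AAAAAT (30.6% against 20.5%) were also among the first 10. Both ACAGTG (11.5% against 4.02%, odds ratio 3.11, adjusted exact p = 2.82e-13) and ACACTG (8.46% against 3.15%, odds ratio 2.85, adjusted exact p = 1.2e-08) were enriched. The words GGAGGA (1.05% against 5.99%) and CTCCTC (1.57% against 6.29%) were depleted. The windows at nuclear summits had a mean GC content of 37.7%, and their flanks 43.6%. A comparison of nuclear summits with flanks matched on GC content was therefore added after these results were seen. Its flanks were drawn with replacement, so 1 flank could count several times and the exact p-values can be too small. The comparison covered the first 10 hexamers, picked from the same summits and flanks and adjusted among themselves, and the fixed sequences. In it, TTAAAA was at 27% of summits and in 21.7% of flanks (odds ratio 1.34, adjusted exact p = 0.000925), ATTTAA at 25.2% against 19.1%, AAATAT at 27.4% against 21.3% and TTTAAA at 17.5% against 11.1%. ATTTTA (24% against 22.5%, adjusted exact p = 0.339) and AAAAAT (29.6% against 27.5%, adjusted exact p = 0.214) no longer passed. GGAGGA (0.895% against 3.36%) and CTCCTC (1.43% against 4.21%) stayed depleted, and CACGTG was at 1.34% of both (odds ratio 1, adjusted exact p = 1).

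**Figure D3:**
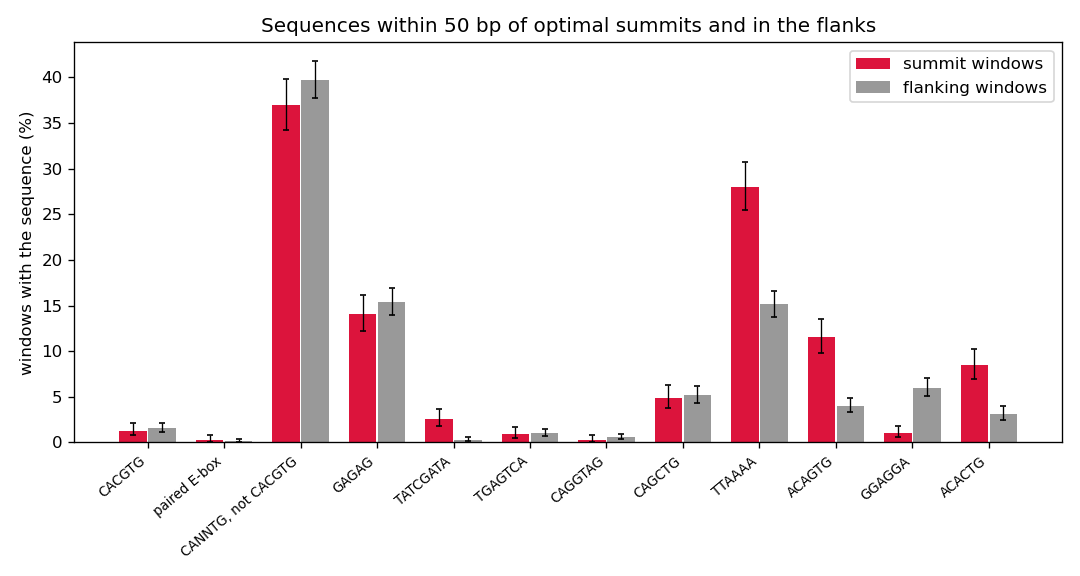
Percent of windows that hold each sequence, within 50 bp of the 1146 optimal summits (red) and in 2289 flanking windows of the same length (grey), with 95% Wilson intervals as bars. CACGTG is at 1.31% of summits and in 1.57% of flanks, while TATCGATA, TTAAAA, ACAGTG and ACACTG are more frequent at summits and GGAGGA less frequent.

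The 15 peaks with CACGTG had a median signal of 130.9, and the 1131 peaks without it 97.8 (difference 33.1, p = 0.0314, permutation test). In 5 parts of the nuclear list of nearly equal size, from strongest to weakest, CACGTG was at 2.23, 3.12, 0.448, 0.448 and 0.448% of summits, which are 5, 7, 1, 1 and 1 peaks. On nuclear peaks only, the difference was 33.7 (p = 0.0206, permutation test). Among the strongest peaks of single replicates it was 13.4 in replicate 5 (p = 0.0339) and −4.75 in replicate 1 (p = 0.285, permutation tests). Within the 573 strongest optimal peaks it was −0.366 (p = 0.979, permutation test). All of these lists are themselves cut on signal.

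The X chromosome held 16.8% of the optimal peaks on X and the large autosomes (95% interval 14.7 to 19.1%), against 19.9% of relaxed peaks outside the optimal list (odds ratio 0.809, p = 0.00909, Fisher's exact test). The relaxed lists themselves differed, with 22.9% of these peaks on X in replicate 5 and 12.6% in replicate 1 (odds ratio 2.05, exact p = 6.39e-236). Chromosome 4 held 601 relaxed peaks in replicate 5 and 264 in replicate 1. Among the 1146 strongest peaks, the X share was 16.2% in replicate 5 and 17.2% in replicate 1 (exact p = 0.534). Against its own relaxed list, replicate 1 had the opposite direction (odds ratio 1.46, exact p = 5.66e-06), and against arm lengths the optimal list had an exact binomial p = 0.411.

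**Figure D4:**
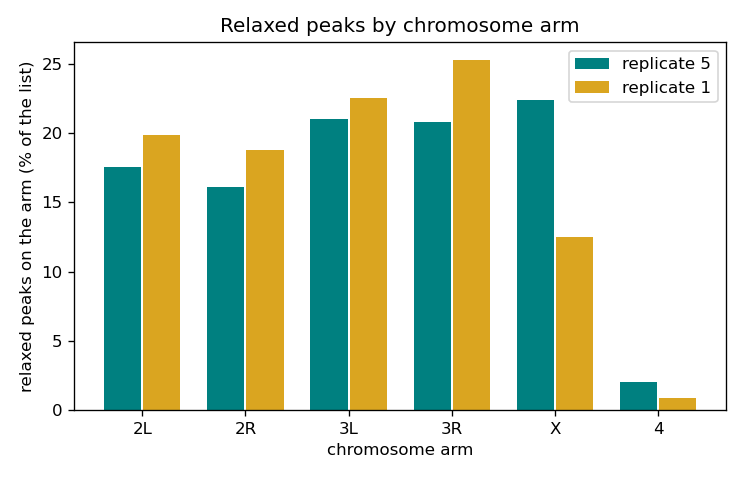
Share of each replicate's relaxed peaks on every nuclear arm, in percent of the list (bars from 0; 29999 peaks in replicate 5, 30000 in replicate 1). X holds 22.4% in replicate 5 and 12.5% in replicate 1, and chromosome 4 holds 2% and 0.88%.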

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

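The nuclear-only repeat and the comparison of nuclear peaks with GC-matched flanks were chosen after the data were seen; the other alternatives were fixed before. The promoter share stayed past its threshold in all alternatives, between 37.9% (whole peaks) and 65.8% (1000 bp), replicate agreement lay between 38.1% and 57.3%, and the ribosomal protein list passed in all 10 alternatives. No paired analysis was possible because there is 1 group. Read depth is unknown, so its effect could not be examined. The stricter list of the 573 strongest optimal peaks had 440 bound genes, 109 enriched hexamers and 1 enriched gene list, with fewer genes by construction. There the E-box odds ratio was 1.37, the E-box signal difference −0.366 and the X odds ratio 0.851 (exact p = 0.175). This list is cut on signal, as the optimal list and the single-replicate lists are, and it spans a narrower range of signal than the optimal list. Sugar transport and gluconeogenesis each had 0% bound and digestive enzymes 5.26%.

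In single replicates the E-box odds ratio ranged from 1.03 to 1.17, the E-box signal difference from −4.75 to 13.4, and the X odds ratio from 0.639 to 1.46, and 1 list was enriched in each. The circadian clock ranged from 10 to 30%, the pentose phosphate pathway from 14.3 to 28.6%, amino acid metabolism from 7.14 to 21.4% and the lysosome list from 8.70 to 21.7%. Fatty acid synthesis ranged from 5.26 to 10.5%, oxidative phosphorylation from 4.55 to 18.2%, muscle markers from 0 to 7.14%, GAGAG from 12 to 16%, TGAGTCA from 0.611 to 1.4% and CAGCTG from 4.01 to 5.24%; none of these lists and sequences was past its threshold. The E-box odds ratio was 1.07 against relaxed summits, 1.15 at promoters against relaxed promoter summits and 1.25 at promoter peaks against flanks, and no alternative passed the threshold. Against GC-matched flanks, other CANNTG sequences (37.2%), GAGAG (14.4%), TGAGTCA (0.985%) and CAGCTG (4.92%) changed direction without passing. Against arm lengths the X odds ratio was 0.932. The rank correlation between the replicates was 0.440 with summits within 50 bp.

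With a TSS distance of 200 bp, 1 list was enriched; gluconeogenesis, neuron and salivary gland lists had 0% and digestive enzymes 5.26%. With whole peaks, 517 genes were bound and 1 list was enriched; digestive enzymes had 5.26%, and glycolysis, the pentose phosphate pathway, sugar-responsive genes, gluconeogenesis, the circadian clock, insulin signalling, neuron and salivary gland lists had 0%. With the reach from 2000 bp before a gene to its end, 1336 genes were bound and 6 lists enriched, without adjustment for gene length. Beside ribosomal proteins and glycolysis, these were the circadian clock (40%), amino acid metabolism (35.7%) and bHLH factors (33.3%, adjusted exact p = 0.0417 for each) and insulin signalling (27.3%, adjusted exact p = 0.0483), while gluconeogenesis had 9.09% and neuron markers 8.33%. Among genes with a relaxed promoter peak, the shares were 12.5% for fatty acid synthesis and for gluconeogenesis, 33.3% for digestive enzymes, 7.14% for bHLH factors and 11.1% for neuron markers, each on the other side of its background than in all genes, with adjusted exact p = 1. Within 25 bp, 76 hexamers were enriched, the paired E-box was at 0.0873% and TGAGTCA at 0.524%; within 100 bp, GAGAG was at 29.2%, TGAGTCA at 2.01% and CAGCTG at 11.6%. The cause of these changes was not tested. Of the promoter peaks of named genes, 59 of the 68 matched in replicate 5 and 53 of the 62 matched in replicate 1 were among the 1146 strongest of that replicate.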

Other observations

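The comparisons in the first 2 paragraphs, the tests of chromosome 4, of mitochondrial coverage, of the distance of mitochondrial summits to CACGTG, and of base composition and promoter background at the enriched words, and the 10 kb counts around Mondo were chosen only after the results were seen. Summits at ribosomal protein genes sat closer to the gene start than those at other bound genes, with each gene counted once. For the 34 bound genes, the median position was −14.5 bp (negative is upstream), and 33 summits (97.1%) were within 100 bp of a TSS. For the other 817 bound nuclear genes the median was −124 bp, and 303 (37.1%) were within 100 bp (median absolute distances 24.5 and 135 bp, p = 6e-05, permutation test). However, 239 optimal summits lay near TSSs of more than 1 gene. Such a summit also counted with its distance to the farther gene, which can lengthen the distances of the other genes. The permutation test treats genes that share a summit as independent. Mitochondrial ribosomal proteins had 7 of 73 promoters bound (9.59%, adjusted exact p = 0.327), translation initiation factors 5 of 44 (11.4%, adjusted exact p = 0.327), aminoacyl-tRNA synthetases 3 of 32 (adjusted exact p = 0.535) and proteasome subunits 4 of 48 (adjusted exact p = 0.539). Cytochrome P450 genes had 1 of 85 and odorant-binding proteins 0 of 51 (adjusted exact p = 0.224 for each).

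Near non-coding genes, 6 of 1117 nuclear optimal summits (0.537%) lay within 500 bp of a tRNA gene, against 0.462% of relaxed summits (p = 0.651, Fisher's exact test). Summits near transposable elements were fewer, at 1.34% against 3.6% (odds ratio 0.364, exact p = 9.28e-06). Near ncRNA genes they were 10% against 7.73% (exact p = 0.0063), and these p-values are not adjusted.

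Mitochondrial peaks led the dm6 list. One candidate explanation is more mitochondrial DNA in the ChIP libraries than in the control, which would raise the whole molecule. Optimal intervals covered 85% of it in dm6 but 12.8% in dm3 (taking the dm6 length for both), and relaxed intervals covered 88.9% in replicate 5 and 18.4% in replicate 1, so the builds and libraries point different ways and the explanation stays open. Binding at CACGTG as the cause is argued against, since the mitochondrial reference sequence has 0 such sites, and so 0% of the 29 summits lay within 50 or 500 bp of one.

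The relaxed lists of the replicates differed in their share on X and 4. A different share of females in the larval pools would shift X by dose. The log2 ratio of replicate 5 to replicate 1 was compared at matched optimal peaks. Its median on X minus that on the autosomes was −0.10 (bootstrap 95% interval −0.22 to 0.06). This lay below a rise of 0.1, a limit set before the test, but a smaller rise is not excluded. That limit also assumes that the signal value follows DNA dose. Since its scale is not given, the test does not exclude a different share of females. The interval covers error over peaks of 1 library per replicate, in a list that favours peaks found in both. Chromosome 4, an autosome that sex leaves at the same dose, differed too (odds ratio 2.61, 95% interval 2.26 to 3.02). Weighting the replicate 5 peaks to the GC content of replicate 1 moved the X share away from replicate 1 (−1.22% of the difference removed), which argues against GC bias at the peaks as the cause. No biological explanation other than sex was tested, and what sets this difference stays open.

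CACGTG was missing near most summits. If summit positions were inexact, it would appear farther out. Among 1102 nuclear peaks without it within 50 bp, the share with it within 150 bp was 2.72%. The share was 3.68% in flanks (difference −0.953 percentage points). The flanks were searched over their whole width, while these peaks were picked to lack it in the middle, so this difference is biased downward and decides nothing. Since only 2.72% had it within 150 bp, inexact positions within that reach cannot account for most of these peaks. Background in the lower part of the list cannot be told apart from absence throughout: CACGTG was at 0.448% of the weakest 223 nuclear summits (95% interval 0.079 to 2.50%), 2.23% of the strongest 224 (0.957 to 5.12%) and 1.61% of flanks (1.17 to 2.22%), and these intervals overlap. Tests on other sequences are in the next paragraph. No ChIP from larvae without the tagged protein was analysed, so signal that does not come from it cannot be told apart here. Whether the tagged protein is at all of these peaks, and which factor or sequence would bring it there, stays open.

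Several hypotheses on sequence and position were also tested. Paired E-boxes were counted by spacer, here as an exact CACGTG beside a second copy with at most 2 mismatches. This is stricter than the fixed sequence, whose mismatches could lie in either copy. A spacer of 5 bp was seen at 3 summits and 0 flanks. It had the highest excess of the spacers from 0 to 12 bp, with adjusted exact p = 0.481, too few sites to decide. The bases beside CACGTG differed between the 15 summit sites and 16428 sites in the nuclear arms. The test was a Monte Carlo chi-square test with draws from the arm frequencies (p = 0.0106, not adjusted for the other tests here). TCACGTGA was at 4 of 15, against 4.01% of all sites. A flanking preference may underlie this, on very few sites, and the base composition of the summits was not accounted for. TATCGATA, ACAGTG and ACACTG stayed more frequent at summits than in flanks matched on GC content. The lowest lower 95% limit of the odds ratios was 2.01. The largest exact p was 1.87e-06 after multiplying by the number of words each was picked from. These flanks were drawn with replacement, and the 11 with TATCGATA were draws of at most 6 windows. The limits are thus too narrow and the p-values too small. The shares were 2.69% against 0.492%, 11.8% against 4.48% and 8.68% against 3.36%, in the order of the words. They argue against base composition alone, though their error is understated. Against summits of other promoter peaks, the odds ratios were 1.56 for TATCGATA, 2.09 for ACAGTG and 1.36 for ACACTG (lowest lower limit 1.03). With the same multiplication, ACAGTG passed (exact p = 0.000388) but TATCGATA (exact p = 0.303) and ACACTG (exact p = 1) did not, so for these 2 words promoter position cannot be told apart from a link to these peaks.

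Around Mondo (2L, 21286078 to 21310050), a 40 kb window held 28 pooled relaxed peaks, more than 99% of windows around other genes of the arm (median 10). Extra copies of the locus in the transgenic line could raise such a count, but its 10 kb parts held 5, 0, 6 and 17 peaks against an arm median of 2. The part with 17 (21308065 to 21318064) held 5 in the 5' end of Mondo, 3 between the genes and 9 in the neighbouring gene crc (21310866 to 21319527), inside which an optimal peak lay (2L, 21313097 to 21313456, signal 138.6). Extra copies and many peaks at these 2 neighbouring genes cannot be told apart here.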
